A study of Homo sapiens with 2 samples.

How the data were processed

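The series holds 2 samples of HCT116 cells, a human colon carcinoma line: 1 chromatin immunoprecipitation (ChIP) library for ATF1 carrying a 3xFlag tag, and 1 input DNA library. Per the labels' protocols, cells were grown with 10% serum and fixed with 1% formaldehyde. Chromatin was sheared to between 200 and 400 bp and precipitated with 5 µg of antibody on protein A/G beads, and the libraries were sequenced on an Illumina HiSeq. The protocol also mentions a nonspecific rabbit IgG, for which no sample was analysed here. Only the peak table of the ChIP library was used; no table of the input was used here, and neither sample has a replicate.

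Per the submitters' processing notes, CASAVA, Bowtie2 and bedtools were used with the hg38 build. The peak caller, its settings, its control and the gene annotation are not given in the sources used here. Per the file headers, the deposited table gives each peak's position, length, summit, number of tags, score, fold enrichment, assigned gene and class. The deposited tag values are whole-number counts per peak, not normalised. The deposited fold enrichment is a ratio to a background that is not specified, and its lowest value is 3. The deposited score has a lowest value of 50, and what it is computed from is not stated. Fold enrichment, score and class are the authors' own values, and were used only to describe and rank peaks within this list.

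The table holds 15064 peaks and 15064 distinct gene names, so each gene appears once, and each peak is assigned to 1 gene. Another 1 line without a peak position was left out. The classes followed the summit: exon and intron peaks all had their summit inside the assigned gene, and upstream and downstream peaks had it outside, within 2 kb. Peaks farther from genes are not part of the table. The total number of reads in either library is unknown, so no depth-based interval can be given, and the 3272654 tags in the listed peaks are not the library's depth. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals over peaks or genes, and intervals on a single peak's tags are exact 95% Poisson intervals. Both cover counting error only. With 1 library there is no test between conditions and no p-value is given.

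Gene positions came from the RefSeq gene table of GRCh38.p14, the same assembly as hg38, with 19974 protein-coding genes on chromosomes 1 to 22 and X. It gives no strand. Of the gene names in the peak table, 13441 matched a current symbol, 724 only an older name and 899 neither (94.0% matched). A peak was called a gene-end peak when its summit lay within 1 kb of either end of a protein-coding gene, and a gene was counted as having one when any peak met this for it, whichever gene the table assigned the peak to. This measure replaced the planned distance to the transcription start, which needs the strand. Observed shares were set beside 1000 random placements, in which each peak was put at a uniformly drawn position within its assigned gene or the 2 kb around it, the only space the table covers; this replaced placement along whole chromosomes. Both replacements were made after the table had been opened.

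Before the data were examined, 19 gene lists with 446 distinct protein-coding genes were fixed; 1 entry that is not a protein-coding gene in the reference was left out. For each list, the share of genes with a gene-end peak was given as a percentile among 10000 random lists of the same size drawn from all protein-coding genes. Matching on promoter CpG content was planned but needs the genome sequence; lists matched on gene length were used as an alternative. A list outside the central 95% of random lists was called low or high. The percentile step was tested on 200 simulated lists of 24 genes from the same 19974 genes: 97.0% of lists with 80% of genes bound, against 45% elsewhere, were called high, and 3.0% of unchanged lists were. Genes named were the 10 strongest gene-end peaks, the 5 strongest peaks over 10 kb from any protein-coding gene end, examples from up to 4 strongest members of each list, and 9 genes chosen in advance (ATF1, BRAF, NRAS, BIRC2, FOS, CCNA2, CREB1, CREM and ATF3). Strength was fold enrichment. Some genes that the rule takes are not reported here. Planned searches for the cAMP response element and other motifs, and the analysis of divergent promoters, were not run, because no genome sequence or strand was used here. Alternatives changed the peak threshold, the window, the use of the summit, the gene set and the matching. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.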

Results

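The study mapped where ATF1, a basic leucine zipper transcription factor of the CREB family, binds the genome of HCT116 colorectal cancer cells. Cells were given ATF1 with a 3xFlag tag, and 1 ChIP library and 1 input DNA library were made. The peak table of the ChIP library listed 15064 peaks on chromosomes 1 to 22 and X. Peaks had a median length of 1551 bp (quartiles 1118 and 2091 bp) and a median of 162 tags (quartiles 60 and 310, range 16 to 3300). Median fold enrichment was 6.97, with quartiles of 5.20 and 9.76 and a maximum of 121.03. There was no replicate, so all values describe this library.

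ATF1 peaks lay more often than random placement at the ends of genes. Of all summits, 56.1% (8448 of 15064, interval 55.3 to 56.9%) were within 1 kb of an end of a protein-coding gene. Random placement of the same peaks within their assigned genes and flanks gave 16.2% on average and at most 17.0%, so the observed share was 3.46 times the random one. Peaks outside their gene were 22.6% of the total, against 19.7% with random placement (1.15 times). Of these, 2996 were upstream and 407 downstream, a ratio of 7.36, and within 1 kb of the gene the counts were 2786 and 210. The upstream summits lay a median of 86 bp from the gene. In total 9593 of the 19974 protein-coding genes (48.0%) had a gene-end peak.

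By the authors' classes, 43.5% of peaks were exonic, 33.9% intronic, 19.9% upstream and 2.70% downstream. Of exonic summits, 67.0% were within 1 kb of an end of the assigned gene, against 32.0% of intronic summits. Upstream peaks had the highest medians, 275 tags and 7.81-fold enrichment, and downstream peaks the lowest, 65 tags and 6.64-fold. Intronic peaks had a median of 86 tags and 6.69-fold enrichment. Of all listed peaks, 3126 (20.8%) were more than 10 kb from any protein-coding gene end. Their median of 49 tags compared with 241 tags for gene-end peaks, while median fold enrichment was 6.90 against 7.49. The table lists 1 peak per gene name and none more than 2 kb from a gene, so these shares and medians describe the listed peaks only.

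The strongest peaks were at gene ends most often. In the top quintile by fold enrichment, from 10.79-fold upwards, 78.6% of summits (interval 77.1 to 80.0%) were gene-end peaks. The 4 lower quintiles lay between 47.0% and 53.8%, with no steady rise among them. Intronic peaks made up 20.5% of the top quintile and 35.1% of the lowest. Ranking by the authors' score or by tags instead gave a rise over quintiles, from 26.1% to 85.6% by score and from 16.4% to 79.8% by tags. Across peaks, tags went with peak length (Spearman's rho 0.82) and hardly with fold enrichment (rho 0.07), and longer peaks had lower fold enrichment (rho -0.23); peaks are not independent replicates.

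**Figure D1:**
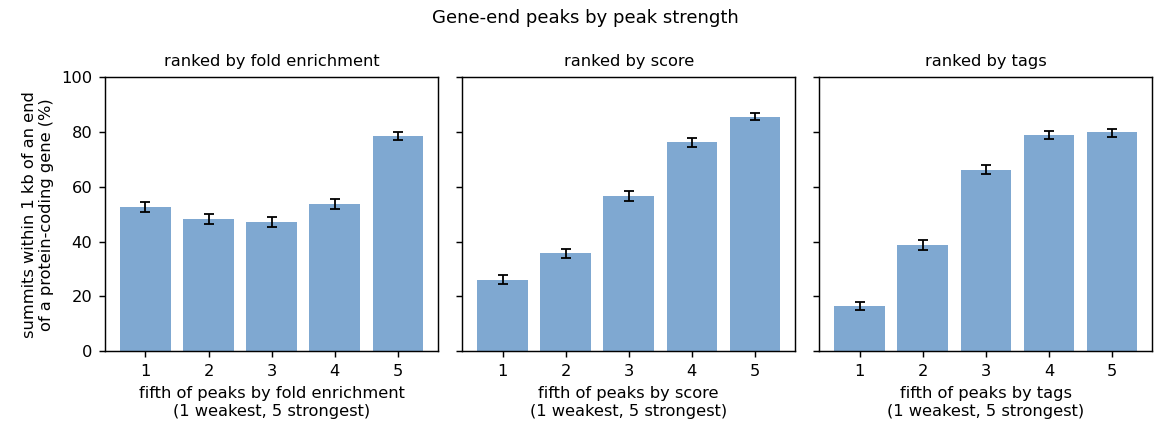
Share of peak summits within 1 kb of an end of a protein-coding gene (y axis, percent) in quintiles of peaks (x axis, 1 weakest to 5 strongest) ranked by fold enrichment, score or tags, with exact 95% binomial intervals. By fold enrichment only the top quintile stands apart, at 78.6%, while by score the share rises from 26.1% to 85.6%.

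The 10 strongest gene-end peaks had fold enrichments between 79.64 and 96.84 and between 227 and 498 tags. The first was at YIPF6, a Yip1-domain gene (chromosome X, 68498282 to 68499699), at 96.84-fold with its summit 66 bp from an end of the gene in the reference. CDADC1 on chromosome 13 followed at 90.00-fold, then C1D on chromosome 2 at 89.65-fold. RAD18, which encodes a ubiquitin ligase of post-replication DNA repair, had 88.56-fold enrichment and 401 tags (chromosome 3, 8962814 to 8964174, exonic). CCNH, the cyclin of the CDK-activating kinase, had 87.37-fold. The others were AASDH, TFIP11, DPH3, CTH and POP4, and the DPH3 peak also lay within 1 kb of OXNAD1. All 10 summits were within 122 bp of a protein-coding gene end.

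The 2 strongest peaks of the whole table were far from protein-coding genes but next to other annotated genes. A peak on chromosome 1 (9427609 to 9429746) reached 121.03-fold with 502 tags, 14 bp upstream of the uncharacterised LOC100506022 and 59478 bp from the nearest protein-coding gene end, that of SPSB1. A peak on chromosome 4 (119454096 to 119455077) reached 104.74-fold with 242 tags, 88 bp upstream of the pseudogene GTF2IP12. Of the remaining 3 peaks of this kind, those at LOC729218 (84.56-fold) and LOC100288069 (58.95-fold) were also upstream, and that at LOC105378179 (73.12-fold) was intronic. How reads that fit several genomic copies were treated is not given in the sources used here, so the value at the pseudogene is uncertain.

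All 9 genes chosen in advance were in the table, and of these BRAF and ATF3 had no gene-end peak. NRAS, a RAS GTPase, had an exonic peak of 30.58-fold and 244 tags (chromosome 1, 114716232 to 114717270), with the summit 89 bp from the listed end of the gene. BIRC2, an inhibitor of apoptosis, had an exonic peak of 28.05-fold and 544 tags (chromosome 11, 102346586 to 102347922), 3 bp from a protein-coding gene end. The peak assigned to BRAF, a RAF kinase (chromosome 7, 140834405 to 140835257), was exonic and 90003 bp from the nearest end of the gene. It held 25 tags (Poisson interval 16.2 to 36.9). Its enrichment of 8.58-fold was above 67.0% of peaks, and its score of 53.24 above 3.97%. The scores of NRAS and BIRC2 were above 94.5% and 99.2% of peaks. Because the table has 1 peak per gene name, it does not show whether BRAF had others.

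ATF1 itself, its relatives CREB1, CREM and ATF3, and the known CREB targets FOS and CCNA2 had fold enrichments above those of 82.0% to 91.6% of all peaks. ATF1 had an intronic peak of 11.57-fold and 577 tags (chromosome 12, 50763115 to 50765299), 281 bp from its listed end. CREB1, its close relative, had 15.48-fold and 602 tags, and CREM, which encodes a further CREB-type regulator, 16.05-fold and 767 tags, in a peak also within 1 kb of CUL2. FOS, an immediate early gene, had an upstream peak of 13.22-fold and 808 tags (chromosome 14, 75276456 to 75280250). CCNA2, the S-phase cyclin, had 11.99-fold and 255 tags, with the summit also within 1 kb of BBS7. The ATF3 peak, 11.32-fold with 683 tags, was exonic and 12085 bp from the nearer of the gene's listed ends. It therefore did not count as a gene-end peak. Only the outer ends of each gene were used, so a peak at a start site inside a gene would not be counted.

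**Figure D2:**
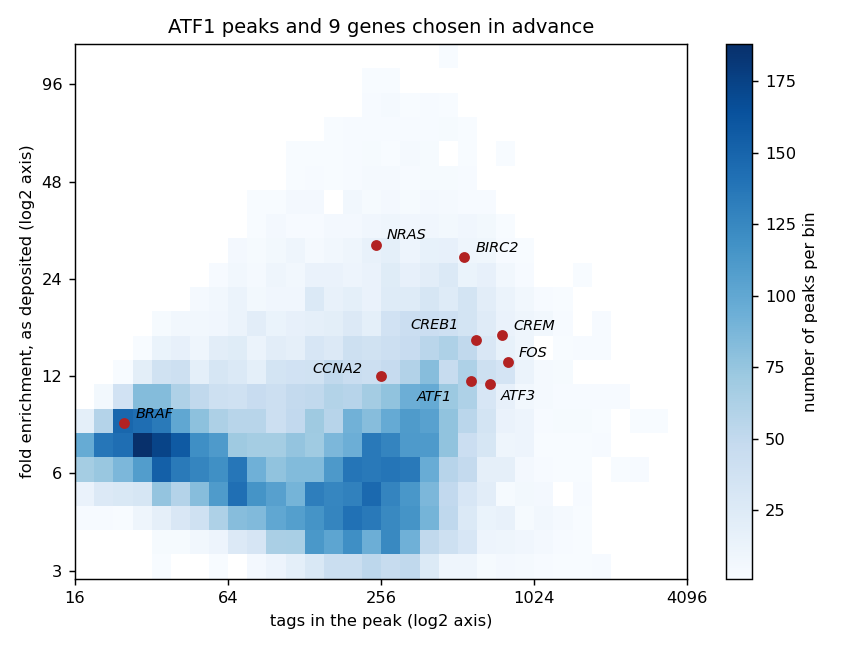
Number of peaks (colour) by tags in the peak (x axis, log2) and deposited fold enrichment (y axis, log2), with the 9 genes chosen in advance as red points. BRAF lies among the peaks with few tags (25), and the other 8 genes hold between 244 and 808 tags.

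Genes of RNA splicing, oxidative phosphorylation, the ribosome, DNA repair, the cell cycle, the unfolded protein response, anti-apoptosis and PI3K-AKT-mTOR signalling had gene-end peaks more often than random gene lists, and markers of 3 of the 4 other cell types less often, with neuron markers the exception. Of the 19 lists fixed in advance, 8 lay above the central 95% of random lists and 3 below it, where chance would put 0.475 on each side. Across all protein-coding genes, 48.0% had a gene-end peak. Expression was not measured, and whether a gene is active in HCT116 was not part of the matching.

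RNA splicing genes had a gene-end peak at 24 of 28, oxidative phosphorylation genes at 28 of 33, ribosomal protein genes at 27 of 33 and DNA repair genes at 27 of 31, each at percentile 100. The splicing factors PRPF4 (39.86-fold, shared with CDC26), SRSF3 (28.00-fold) and SF3B1 (21.80-fold) were among them. In the respiratory chain, the peak at NDUFA1 had 37.46-fold enrichment and was shared with RNF113A, and NDUFV1 had 23.53-fold. RPL18 had 29.84-fold, in a peak shared with SPHK2, and RPS13 27.12-fold. DNA repair genes included FANCD2, of the Fanconi anaemia pathway (58.20-fold), RAD51C (42.71-fold, shared with TEX14 and IGBP1C) and ATM, a DNA damage kinase (34.01-fold, shared with NPAT). Cell cycle genes had a peak at 22 of 28 (percentile 99.95), with AURKA at 29.44-fold, a peak shared with CSTF1, and MAD2L1 at 18.18-fold. Genes of the unfolded protein response and endoplasmic reticulum chaperones had one at 18 of 24 (percentile 99.57), including SEL1L (25.20-fold), the chaperone HSPA5 (23.30-fold) and DDIT3 (21.36-fold, shared with MBD6 and LOC128125814). Among the 1516 strongest peaks the DNA repair and cell cycle calls ended (percentiles 83.4 and 87.1). When any gene named in the table was counted, a setting chosen after the data were seen, those of oxidative phosphorylation, ribosomal protein and splicing genes ended (percentiles 84.4, 74.4 and 97.3).

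Anti-apoptotic genes had a gene-end peak at 15 of 16 (93.8%, interval 69.8 to 99.8%, percentile 99.985), all but BCL2A1, which is named after its value was seen. BCL2L2 (28.35-fold, shared with the readthrough gene BCL2L2-PABPN1), BIRC2, DAD1 (17.15-fold) and API5 (15.19-fold) were the strongest. The peaks named for anti-apoptotic genes had a median of 6.87-fold, within the range of random genes of the table (6.97, percentile 46.15). Pro-apoptotic genes had one at 11 of 19 (57.9%, interval 33.5 to 79.7%, percentile 80.5, or 97.9 and so high with a 5 kb window), led by CYCS, which encodes cytochrome c (23.65-fold, shared with SPMIP4), and PMAIP1 (11.80-fold). The intervals of these 2 lists overlap, which is not a test of the difference between the lists, and none was run. PI3K-AKT-mTOR genes had a peak at 16 of 18 (percentile 99.97), with RHEB at 12.62-fold and PDPK1 at 10.48-fold. The peaks named for PI3K-AKT-mTOR genes had a median of 6.27-fold, within the range of random genes of the table (6.99, percentile 20.4). When only the 7556 stronger peaks were used, the anti-apoptotic list fell to percentile 96.8 and the PI3K-AKT-mTOR list to 50.2, so both calls ended. Among the 1516 strongest peaks the anti-apoptotic list was high again (97.94), and the PI3K-AKT-mTOR list had none of its 18 genes bound.

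RAS-MAPK genes had a gene-end peak at 15 of 23 (percentile 94.8). NRAS and SOS2 (29.55-fold, shared with VCPKMT) were the strongest, whereas BRAF was among the 8 without one. WNT pathway genes had one at 16 of 25 (percentile 94.3), with GSK3A at 18.61-fold and LGR5 at 9.83-fold. ATF and CREB family genes and coactivators reached 14 of 21 (percentile 95.4), with ATF7 at 15.11-fold, in a peak shared with the readthrough gene ATF7-NPFF, and ATF2 at 14.62-fold. Classical targets of the cAMP response element had a gene-end peak at 17 of 32 (percentile 71.6). NR4A2 (21.80-fold, 978 tags), CREM (16.05-fold), RGS2 (15.05-fold) and DUSP1 (14.99-fold) led them. When any gene named in the table was counted, 28 of these 32 were included (percentile 99.935). That setting also made the circadian clock (99.955), ATF and CREB (99.85), WNT (97.53) and pro-apoptotic (98.4) lists high. The peaks of the CRE targets were long, with a median of 2754 bp, above all random gene sets of the table. Circadian clock genes had a gene-end peak at 10 of 19 (percentile 65.1), with HLF at 20.96-fold. Intestinal epithelial genes had one at 11 of 21 (percentile 65.6), among them ELF3 (10.43-fold) and the peak shared by KRT8 and KRT18 (8.61-fold).

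Hepatocyte markers had a gene-end peak at 2 of 21 (percentile 0), lymphocyte markers at 1 of 19 (percentile 0.01) and fibroblast and muscle markers at 4 of 21 (percentile 0.4). The stronger of the hepatocyte peaks, at TF (13.25-fold), was assigned by the authors to its neighbour TOPBP1. The lymphocyte peak was at ZAP70 (7.81-fold). Of the fibroblast and muscle genes, MYOG had 6.69-fold enrichment. With a 5 kb window the calls of the lymphocyte and the fibroblast and muscle markers ended (percentiles 22.1 and 9.72). The latter also ended when any overlap with the window (3.26) or any gene named in the table (5.05) was counted. Neuron markers did not stand apart, with 9 of 20 (percentile 39.5), but the peaks named for neuronal genes had a low median fold enrichment of 5.16 (percentile 1.79 among random gene sets of the table). SYT1 had the strongest neuronal gene-end peak, at 10.83-fold.

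**Figure D3:**
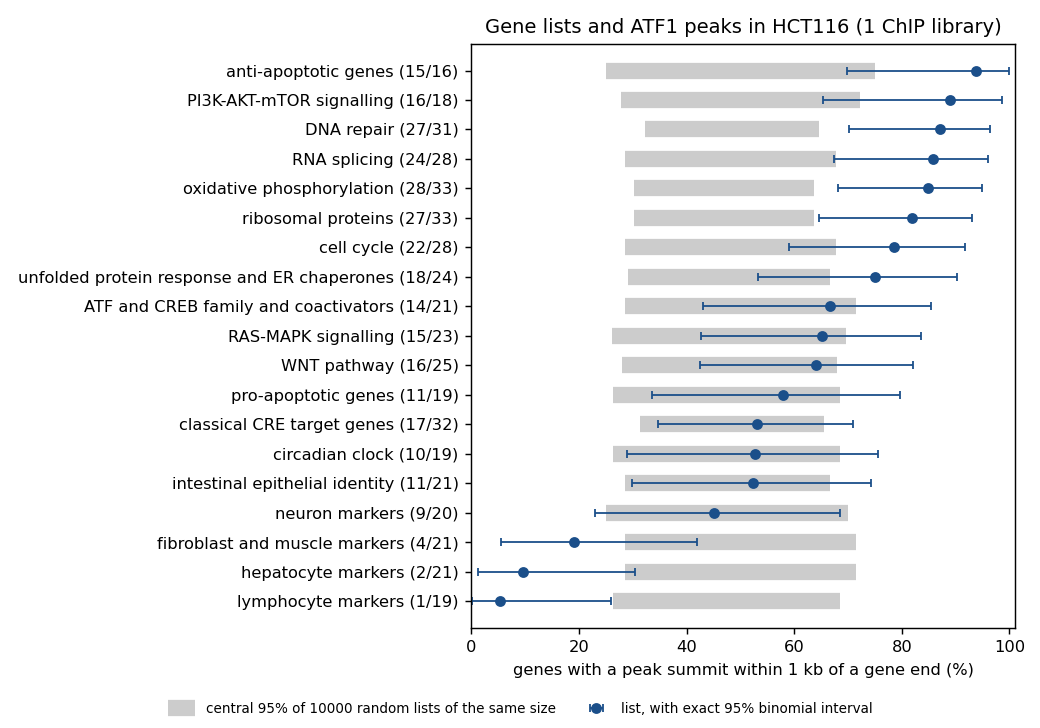
Share of genes with a peak summit within 1 kb of a gene end (x axis, percent) in the 19 gene lists (y axis, genes with a peak over genes in the list). Points have exact 95% binomial intervals, and grey bars hold the central 95% of 10000 random lists of the same size; 8 lists lie above their bars and 3 below.

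Chromosome X had fewer listed peaks per protein-coding gene than each of the 22 autosomes. This did not hold for gene-end peaks alone, where chromosome X had 32.7 per 100 protein-coding genes and chromosome 21 had 31.0. The autosomes had between 65.5 (chromosome 11) and 94.4 (chromosome 13) peaks per 100 protein-coding genes, with a median of 78.1. Chromosome X had 46.2 (Poisson interval 41.8 to 51.0), and its peaks held a median of 96.5 tags, against 116 to 201 on the autosomes. Its median fold enrichment, 8.32, was above the autosomal range of 6.40 to 7.37. Listed peaks per Mb of chromosome were counted up to the end of the last annotated gene. Chromosome 19 had the most, 17.7, and chromosome X the fewest, 2.51. The table holds as many gene names as peaks (15064), so these are counts of listed gene names, some of them not protein-coding. Peaks per Mb therefore depend on how densely genes lie, and neither rate measures the density of binding.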

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

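The values below show how far the results move with settings. Alternatives chosen after seeing the data were the 11671 peaks of at least 5-fold, genes of up to 8156 bp, ranking by score or tags, lists matched on gene length, and counting any gene named in the table. The ratio of the gene-end share to random placement was above 1 in each setting with its own placement, and its size varied. The share was 62.3% of the 7556 stronger peaks (3.83 times random placement), 85.2% of the 1516 strongest (4.35 times) and 57.0% of peaks of at least 5-fold (3.57 times). It was 49.0% with a 500 bp window (5.69 times), 72.0% with 5 kb (1.63 times), 62.6% for any overlap with the window, 65.8% with ends of all annotated genes (2.78 times) and 61.0% for genes of up to 8156 bp (1.64 times). Among the stronger 7556 peaks 30.2% were intronic, 23.2% upstream and 2.32% downstream. Among the strongest 1516 the shares were 51.8% exonic, 16.5% intronic, 31.1% upstream and 0.528% downstream, and for genes of up to 8156 bp 40.1%, 26.9%, 26.6% and 6.41%. The gap in gene-end share between top and bottom quintiles was 25.8 percentage points by fold enrichment, 59.6 by score and 63.4 by tags. Merging peaks within 500 bp left 14991, and dropping the longest left 14608. The count of lists above random stayed between 6 and 10, except for 5 among the strongest 1516 peaks, where 0 lay below. That 0 was fixed by the setting, in which a list with no bound gene still lies between percentiles 3.17 and 13.1, so it says nothing about the low calls. There the PI3K-AKT-mTOR list, with 0 bound genes, was at 10.9. With a 5 kb window 1 list lay below. Of 152 list values, 131 stayed inside or outside the central 95% of random lists as before, 6 gained a call, 14 lost it on the same side of the random median, and 1, the PI3K-AKT-mTOR value just given, lost it on the other side. The 14 include the hepatocyte, lymphocyte, and fibroblast and muscle calls among the strongest 1516 peaks, which that setting could not keep. With gene-end peaks only, the chromosomes ranged from 31.0 (chromosome 21) to 53.0 (chromosome 18) peaks per 100 protein-coding genes, and with other peaks only from 13.6 (X) to 51.2 (chromosome 13). The causes of these shifts were not tested. Motif settings, CpG-matched lists, divergent promoters and the CRE position were not run, for want of sequence or strand. The read depth of the libraries is unknown, so the absence of a peak does not show the absence of binding.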

Other observations

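The gene families below were set by symbol after the table had been opened; the developmental family was included because such genes were seen among the weakest peaks. The test of copies of chromosome X, the matching of families on gene length and the count without the weakest peaks were chosen after results had been seen, and no biological explanation was tested, since there is a single condition. A gene-end peak was present at 46 of 55 translation initiation factor genes, 33 of 40 proteasome subunit genes and 57 of 77 mitochondrial ribosomal protein genes, each at percentile 100 of random lists. Vacuolar ATPase genes had one at 17 of 24 (percentile 98.7) and ZNF zinc finger genes at 274 of 517 (percentile 98.8). Anaphase-promoting complex genes (10 of 14, percentile 95.6), RNA polymerase subunit genes (20 of 33, percentile 92.2) and canonical histone genes (37 of 73, percentile 67.6) were within the range of random lists. Against random lists matched on gene length, histone genes were at percentile 99.98, ZNF genes at 88.0 and vacuolar ATPase genes were at 97.9. The 26 histone genes named in the table had a median enrichment of 10.97-fold, also at percentile 99.98.

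Gene-end peaks were rare in 4 families of receptors, adhesion proteins and defence peptides. There were 2 among 392 olfactory receptor genes, 2 among 28 taste receptor genes, 0 among 65 protocadherin genes and 0 among 45 defensin genes, each at percentile 0. Keratin genes had 11 of 50 (percentile 0.01). Random lists were drawn gene by gene. Whether genes of a family lie side by side was not taken into account, here or in the other families.

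Peaks upstream of genes lay more often at the gene end with the lower coordinate. Of 2996 upstream peaks 60.4% (interval 58.7 to 62.2%) lay there, rising from 55.0% in the shortest quintile of genes to 65.0% (60.8 to 69.0%) in the longest, and downstream peaks went from 57.5% to 89.7%. Uneven numbers of genes on the strands, if alike at all gene lengths, are argued against as the whole cause by the rise of 10.0 percentage points (4.88 to 15.6) between those quintiles. Whether they are alike was not checked, since the reference gives no strand. A partial role stays open, with the shortest quintile at 55.0% (51.5 to 58.5%). Keeping the weakest peak is argued against because it predicts no side, although the ratio of median fold enrichment in the longest to the shortest quintile, 0.919 (0.836 to 0.968), went its way. From the shortest to the longest quintile the medians of upstream peaks were 7.61, 8.01, 8.41, 8.415 and 6.99, so only the longest lay below the shortest. A candidate explanation is that the lowest-coordinate peak of each gene was kept when the table was reduced to 1 peak per gene. If so, BRAF, which is transcribed towards lower coordinates, would be listed with its interior peak of 25 tags even if a promoter peak existed. Peaks at the high-coordinate end of other long genes could likewise be missing. Which way this would move the gene-end shares was not tested.

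Chromosome X had fewer tags for a given enrichment. Tags per kb divided by fold enrichment, a rough measure of local background, had a ratio of medians of 0.592 (bootstrap interval 0.535 to 0.649) to the autosomes, and X lay below all 22 of them. Weaker or narrower peaks on X are argued against as the whole cause, since after matching on fold enrichment and length the ratio was still 0.821 (0.731 to 0.924). By median fold enrichment the peaks on X were higher, 8.32 against 6.40 to 7.37 on the autosomes, and the measure divides by it. Fewer DNA copies of X than of the autosomes is a candidate explanation for the unmatched ratio, and how much of it they would account for stays open, since the matched ratio is nearer 1. No read depth of the input was used to test it directly, and fewer copies would also lower the chance of calling a peak there.

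Developmental transcription factor genes (HOX, SOX, PAX, IRX and related) had wide peaks of low enrichment. A gene-end peak was present at 80 of 190 (percentile 5.16, or 32.3 with matching on gene length), and the 120 named in the table had a median peak length of 2529 bp (percentile 100) and a median of 4.98-fold. Low enrichment of wide peaks in general could lie behind this. Random genes matched on peak length had a median of 6.33-fold, the family was at 0.787 of that, and 0 of 10000 matched lists were as low. Without the 3 members among the 100 weakest peaks, the other 117 had a median of 5.02-fold against 6.32, again with 0 of 10000 lists as low. Because the family was chosen after such genes were seen among the weakest peaks, neither comparison decides against that explanation. Base composition and the openness of these regions in the input stay open, since neither was measured here.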
